A study of Mus musculus with 5 samples.

How the data were processed

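Plasma cells, the antibody-secreting end stage of B cells, were sorted from unimmunized male C57Bl6/N mice and profiled by single-cell RNA sequencing. Per the labels, cells with high CD138 (syndecan-1) and without Ly6g or CD11c were sorted in 2 rounds, cells of 3 mice were pooled for each sample, and libraries were made with the 10x Genomics 3' chemistry, version 2. The sort divided the cells by B220, a form of the surface protein CD45 (gene Ptprc), and by uptake of 2NBDG, a fluorescent glucose analog. There were 5 samples, 1 per group: splenic B220+2NBDG-, splenic B220-2NBDG-, splenic B220+2NBDG+, splenic B220-2NBDG+ and bone marrow B220-2NBDG+ plasma cells. Each group was therefore 1 library, cells were not treated as replicates, and none of the 5 comparisons between groups had a replicate check.

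The deposited tables hold raw UMI counts, as whole numbers per gene and cell barcode, with 33456 genes in each table. Per the submitters' processing notes the authors used Cell Ranger 2.1 and the GRCm38 genome build. The transcript annotation and the filter that chose the deposited barcodes are not given in the sources used here. Of the 33456 gene identifiers, 32655 were found in GENCODE M21, from which gene coordinates (GRCm38, counted from 1), current symbols and 266 immunoglobulin genes were taken. A 3' library counts transcript ends, and a read shared by near-identical genes can be assigned to either copy or lost.

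All 5476 deposited barcodes passed a filter of at least 500 UMIs, at least 200 genes and less than 10% mitochondrial UMIs. Cells of all libraries were clustered together without immunoglobulin genes in scanpy 1.11.5 with 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1 (leidenalg 0.10.2, igraph 0.11.9). Clusters were named from marker lists for 13 cell types. A cluster of 16 cells led by Ms4a4b, Trbc2 and Cd3d was called T cell-like and left out, which left 5460 cells; a cluster of 199 cells was called cycling cell-like and kept. Scrublet, run per library within scanpy, called 82 doublets (1.50%), which were kept and left out only as an alternative.

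For each comparison, UMIs were summed over the cells of a library and divided by the library's non-immunoglobulin UMIs to give CPM values. Immunoglobulin transcripts were left out of this total because they took a large share of the UMIs of a plasma cell. A gene was counted as higher or lower when it had at least 25 CPM and 50 UMIs in the higher library and a CPM ratio of at least 2. For the ratio, any count below 3 UMIs was raised to a floor of 3 UMIs. No significance test was made for these ratios. Their intervals are exact 95% conditional binomial intervals of the 2 counts and cover counting error only, as do the exact Poisson intervals of a CPM and the exact Clopper-Pearson intervals of a share of cells. The median log2 ratio of each of 20 gene lists was placed among 10000 random lists of the same size drawn from 20 bins of mean expression, and a list was called apart when its percentile was below 2.5 or above 97.5. Members with a mean below 10 CPM were not used. Of 535 genes in the program and cell-type lists, 533 matched the tables; Cr2 and Lilrb4a were not analysed here.

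The text names, for each comparison, the 10 genes with the highest and the 10 with the lowest ratio past the rule, up to 10 genes per direction that passed it in both comparisons of a pair, members of the gene lists, and a fixed set that includes Sdc1, Ptprc, Slc2a1, Hk2, Slc3a2, Tnfrsf17, Jchain and Mki67. These lists, thresholds and naming rules were chosen before the data were examined. In the bone marrow comparison Mt1, Mt2, Ccr9, Ccr10, H2-Aa, Ggh and Plac8 were named after their values were seen. Among the highest and lowest genes, those split between libraries in the same way in every comparison are described once, together.

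A cell was called by isotype when it held at least 10 heavy-chain constant UMIs and at least 70% came from 1 gene. Kappa or lambda was called by the same rule. Each IgG subclass gene was judged alone, and cells called for any subclass were counted together as IgG. Ighd, Iglc1 and Iglc3 were not analysed here. A cell was called cycling when it held at least 3 UMIs of the cell cycle list after being thinned to 1000 non-immunoglobulin UMIs. After the data were seen, the UMIs of cells called IgM, IgG and IgA were summed within each library and compared across the 5 libraries with edgeR 4.0.16 (R 4.3.3) by the quasi-likelihood test, with TMM factors, filterByExpr and the library as a block, and Benjamini-Hochberg adjustment at 0.05. No label says that the libraries came from separate animals, so p-values from this test measure the spread between these 5 libraries.

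Both calculations were tested on simulated data drawn from the real means with 200 changed genes. Of 50 genes changed 2-fold in each comparison, 30, 23, 23, 26 and 22 passed the rule in the order 2NBDG in B220+, 2NBDG in B220-, B220 in 2NBDG+, B220 in 2NBDG- and bone marrow (3807, 3572, 3602, 3802 and 3323 genes). All 50 genes changed 3-fold passed in each comparison and no unchanged gene did. A planted list of 30 genes shifted by 0.5 log2 was found in all 5. Of 20 unchanged lists, 1, 0, 1, 2 and 0 were called apart in the same order. Counts for the 5 comparisons were drawn with counting error only, and the planted list was shifted in the computed ratios. These simulations therefore do not measure false calls from variation between pools or libraries. In the IgA against IgM simulation on 7655 genes, 40 of 50 genes changed 2-fold and 49 of 50 changed 3-fold were called, with 2 false calls.

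Alternatives chosen beforehand were CPM over all UMIs, TMM factors on the 5 sums, the mean of each cell's CPM, a 1.5-fold threshold, no CPM minimum (10 UMIs), no cell filter, T cell-like cells kept, doublets left out, cycling clusters left out, libraries thinned to the smallest, other Leiden resolutions (0.5 and 2), other dominance thresholds (50% and 90%) and minimum UMIs, and other thinning depths. Alternatives added after the data were seen were leaving out Jchain, cells called IgM alone, clusters with few genes per cell left out, genes of the library split left out, the other B220- splenic library as partner of bone marrow, a minimum of 100 Igkv UMIs, and, for the isotype test, no block, no filter, no TMM factors, DESeq2 1.42.0, the cluster led by Anxa2 left out and each library left out in turn. Further tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19 and matplotlib 3.10.9.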

Results

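Single-cell transcriptomes of plasma cells from unimmunized mice were compared between populations sorted by B220 and by uptake of the fluorescent glucose analog 2NBDG, and between spleen and bone marrow. The 5 groups had 1 library each, pooled from 3 mice, with about 1000 cells per subset stated by the submitters. The splenic B220+2NBDG- library held 1222 barcodes and 12635338 UMIs, splenic B220-2NBDG- 1296 and 13951244, splenic B220+2NBDG+ 1126 and 15591435, splenic B220-2NBDG+ 894 and 9451886, and bone marrow B220-2NBDG+ 938 and 14664193. Median UMIs per cell were 9824, 9912, 13772, 10345 and 15502 in the same order, with between 1285 and 1600 genes per cell. With 1 library per group there was no replicate error against which to set a difference, so ratios between libraries are given with 95% counting intervals and without p-values.

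The cells carried the transcripts of plasma cells. Sdc1, which encodes the sorted protein CD138, lay between 403 and 609 CPM in the 5 libraries, and Xbp1, a transcription factor of secretory cells, between 3237 and 4373 CPM. The 16 plasma cell markers together made up 135892 CPM in B220+2NBDG- cells and 331912 CPM in bone marrow, most of it Jchain, the joining chain of polymeric antibodies, at 100354 and 296793 CPM. A T cell-like cluster held 9 of 1222 B220+2NBDG- cells (0.736%, exact 95% interval 0.337 to 1.39), 6 of 1126 B220+2NBDG+ cells and 1 of 1296 B220-2NBDG- cells. No cell of the B220-2NBDG+ spleen or bone marrow library fell in it, which allows shares of up to 0.336% and 0.320% (3 counts of the total). Summed markers of neutrophils, mast cells, megakaryocytes, dendritic cells, natural killer cells and stromal cells stayed at or below 35.5 CPM in each library, and those of erythroid cells between 41.0 and 69.5 CPM. Several other marker lists were led by genes that plasma cells express in every library: the macrophage list by Ctss (652 to 1423 CPM), the plasmacytoid dendritic cell list by Ly6c2 (517 to 2266 CPM), the T cell list (127 to 197 CPM in sum) by Cd28 (92.2 to 162 CPM) and the B cell list (3139 to 4708 CPM in sum) by Ly6d and Cd79a. The plasmacytoid list summed to 2871 CPM in bone marrow against 1065 to 1854 CPM in the spleen, and the cycling list to 2601 CPM in B220+2NBDG- cells against 226 to 462 CPM elsewhere.

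Immunoglobulin genes took 47.0% of UMIs in B220+2NBDG- cells and 63.3%, 64.8%, 58.2% and 61.5% in the splenic B220-2NBDG-, B220+2NBDG+ and B220-2NBDG+ cells and bone marrow. Jchain took a further 10.0% of the non-immunoglobulin UMIs in B220+2NBDG- cells and 19.4% to 29.7% in the other libraries. The choice of total therefore moved the ratios of all genes. Scaling to all UMIs shifted the median log2 ratio by -0.59 for 2NBDG in B220+ cells, 0.19 for 2NBDG in B220- cells, -0.25 for B220 in 2NBDG+ cells, 0.53 for B220 in 2NBDG- cells and -0.12 for bone marrow. Leaving out Jchain shifted it by 0.16, 0.08, -0.14, -0.23 and 0.05 in that order, and TMM factors by -0.11 for B220 in 2NBDG- cells and 0.16 for bone marrow. The percentiles of gene lists compare each list with matched genes of the same libraries.

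The libraries also divided along a line that no gate follows. In B220+2NBDG- and splenic B220-2NBDG+ cells, 10 genes were at least 2-fold lower and 8 at least 2-fold higher than in each of the other 3 libraries, a comparison chosen after the data were seen. The ribosomal pseudogene Rps18-ps3 had 271 and 85.1 CPM in these 2 libraries against 4.78 to 12.4 CPM in the others. Lower in these libraries were Nme2, Atp5g2, Atp5l, Hist2h2aa1 and the mitochondrial gene mt-Atp8, and others higher were Rpl7a-ps5, Rps10-ps1, Mir682 and Rnaset2a. Each of the 5 comparisons pairs a library of one side with a library of the other, so all 18 genes are among the calls of each comparison, and they fill many places among the highest and lowest genes. Rnasek, Dynlt1b, Gm15013 and Gm10076, which are not among the 18, also ranked there.

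The isotype of the cells differed between the sorted populations. IgM cells made up 83.3% (81.2 to 85.3) of B220-2NBDG- cells, 62.4% (59.1 to 65.6) of splenic B220-2NBDG+ cells, 58.3% (55.5 to 61.1) of B220+2NBDG- cells and 39.1% (36.2 to 42.0) of B220+2NBDG+ cells. IgG cells were 34.4% (31.7 to 37.1) and 49.3% (46.3 to 52.3) of the B220+2NBDG- and B220+2NBDG+ cells, but 5.71% (4.51 to 7.12) and 13.1% (10.9 to 15.5) of the splenic B220- cells without and with 2NBDG. With 90% dominance instead of 70% the IgG shares of the B220+ libraries were 32.6% and 19.1%, so their order depends on this threshold. The threshold applies to a single gene, so a cell with UMIs of several IgG subclasses can fail it. IgG2c was the leading subclass in the B220+ libraries, at 20.8% and 27.6% of cells. IgA cells were 59.0% (55.7 to 62.1) of bone marrow cells and 23.9% (21.2 to 26.9), 10.4% (8.81 to 12.2), 8.39% (6.84 to 10.2) and 6.35% (5.04 to 7.87) of the splenic B220-2NBDG+, B220-2NBDG-, B220+2NBDG+ and B220+2NBDG- cells. The IgA share of B220+2NBDG+ cells was also lower with 90% dominance. IgE cells numbered 1 in each of the 2NBDG- libraries and 0 in the others. Lambda light chains, called from Iglc2 alone, marked 9.41% (7.85 to 11.2) of the 1243 B220-2NBDG- cells called kappa or lambda. In the other libraries they marked 0.537% to 2.05% of such cells. Cells with other lambda constant genes could not be called lambda, so these shares may be too low. The isotype shares come from 894 to 1295 cells per library. Pools of few mice can hold large clones, and no replicate shows how far the shares vary between pools.

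**Figure D1:**
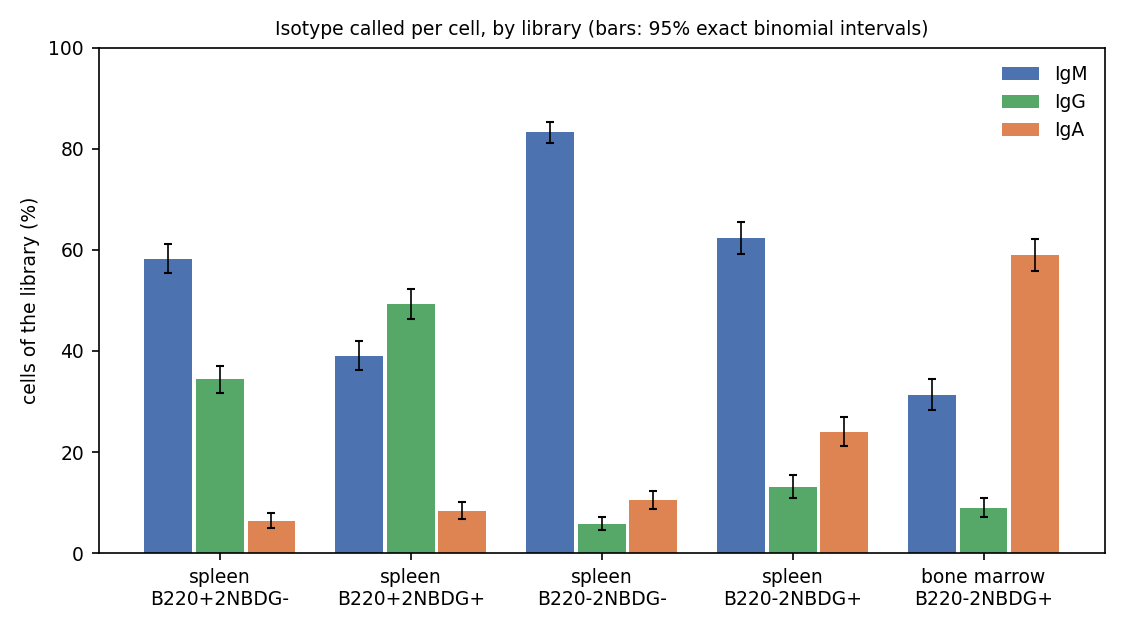
Share of cells called IgM, IgG or IgA in each of the 5 libraries, in percent of cells, with exact 95% binomial intervals that cover counting error only. IgG was highest in B220+2NBDG+ cells (49.3%), but not with 90% dominance, and IgA in bone marrow (59.0%).

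Among splenic B220+ plasma cells, uptake of 2NBDG went with lower levels of cell division genes. Il4i1, a secreted amino acid oxidase, was 22.1-fold lower in 2NBDG+ cells (10.5 to 55.7; 7 against 189 UMIs), the mitotic kinase Aurka 19.6-fold lower (10.8 to 39.7), the survivin gene Birc5 16.8-fold lower (12.5 to 23.2) and the proliferation marker Mki67 4.27-fold lower (3.41 to 5.39). Ccnb2, Tpx2, Tacc3 and Cdca8, which act in mitosis, were 15.2-fold to 16.8-fold lower. Higher in 2NBDG+ cells were the immediate early gene Fosb (4.15-fold, 3.20 to 5.43), the polarity gene Crb3 (3.53-fold, 2.58 to 4.91) and, below the 2-fold rule, Jchain (1.93-fold) and the amino acid transporter subunit Slc3a2 (1.85-fold, 1.79 to 1.91). Slc2a1 and Hk2, low-count genes of glucose uptake, were not higher in these 2NBDG+ cells. The transporter gene Slc2a1 was 1.57-fold lower in 2NBDG+ cells (1.09 to 2.27; 48 against 92 UMIs) and hexokinase Hk2 1.93-fold lower (1.35 to 2.82).

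Of 3982 genes tested in this comparison 48 were at least 2-fold higher and 184 lower, 10 and 8 of them genes of the library split. All 31 measured cell cycle genes were 2-fold lower, with a median log2 ratio of -3.17 against -0.14 for matched random lists. The glycolysis list had a median of -0.54 (percentile 0.07), led by Eno1 (-1.19) and Gapdh (-1.13), and the tricarboxylic acid cycle list -0.45, with all 22 members below 0 (percentile 0.14). Both of these lists lost their place apart from random lists when the cycling clusters were left out and with the mean over cells, and the glycolysis list also among IgM cells alone. Higher than matched lists were the immediate early genes (0.41, percentile 100), integrated stress response (0.31), plasma cell identity (0.20), mitochondrially encoded (0.15) and autophagy (0.13) lists, and the median of each of these turned negative when scaled to all UMIs; the autophagy list did not stand apart among IgM cells alone. The split of calls was 8 higher and 708 lower when scaled to all UMIs, and 88 higher and 157 lower without Jchain. With the cycling clusters left out 63 genes were lower, and Mki67 was at -0.36 log2.

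Among splenic B220- plasma cells, those that took up 2NBDG had lower levels of genes of B cells and of antigen presentation. Anxa2, a calcium-dependent membrane binding protein, was 52.1-fold lower (23.7 to 143; 6 against 405 UMIs), the replication factor Pclaf 17.2-fold lower (7.72 to 47.8) and the lipid carrier Apoe 13.3-fold lower (10.7 to 16.8). Within IgM, IgG and IgA cells Anxa2 was at -2.45, -1.07 and -7.7 log2. With 6 UMIs in all 2NBDG+ cells, these values rest on counts at or near the floor. A cluster led by Anxa2 held 95 of the 135 IgA cells of the B220-2NBDG- library and 2 of the 214 of the splenic B220-2NBDG+ library, so much of the Anxa2 ratio came from these cells. The transcription factor gene Hes1 was 4.07-fold higher (2.99 to 5.62). Slc2a1 was near equal at 1.06-fold lower (0.643 to 1.75; 30 against 41 UMIs), and Hk2 was 2.16-fold higher (1.22 to 3.90) on 35 against 21 UMIs.

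Here 33 genes were higher and 78 lower of 3687 tested, 8 and 10 of them genes of the library split. The MHC class II list (median -0.61, 7 of 7 members below 0), the B cell identity list (-0.60, 12 of 13 below 0), the cell cycle list (-0.71, 9 of 9 below 0), the homing list (-0.22) and the survival list (-0.22) were lower than matched lists. Plasma cell identity (0.14) and mitochondrially encoded genes (0.14) were higher. Neither the glycolysis list (-0.10, percentile 29.8) nor the tricarboxylic acid cycle list (-0.11, percentile 29.8) stood apart. The cell cycle list lost its place without the cycling clusters, the homing, survival and plasma cell identity lists among IgM cells alone, the homing list also without Jchain, and the survival list also when scaled to all UMIs, with the mean over cells and without predicted doublets. Scaled to all UMIs, 33 genes were higher and 31 lower.

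A set of 23 genes differed the same way with 2NBDG in both pairs of splenic libraries, which share no library. Higher in 2NBDG+ cells in both were Slpi, Mt2, Ifitm3, Lgals3bp, Tmem176a and Tmem176b. Slpi (ENSMUSG00000017002; chromosome 2, 164354070 to 164389095), a secreted protease inhibitor, was 2.1-fold higher in B220+ cells (2.08 to 2.12; 23939 against 11382 CPM) and 2.64-fold higher in B220- cells (2.60 to 2.69). The metallothionein gene Mt2 (ENSMUSG00000031762; chromosome 8, 94172664 to 94173568) was 3.15-fold (2.43 to 4.11) and 2.86-fold (2.51 to 3.26) higher, and the interferon-induced membrane gene Ifitm3 2.35-fold (1.99 to 2.77) and 2.29-fold (1.95 to 2.69). The 17 genes lower in both included Anxa2 (ENSMUSG00000032231; chromosome 9, 69453620 to 69491795), which was 4.93-fold lower in B220+ cells (3.96 to 6.21), the intermediate filament gene Vim (4.23-fold, 3.51 to 5.12, and 4.2-fold, 3.12 to 5.76), Apoe (3.19-fold in B220+ cells, 2.99 to 3.41) and the chromatin and replication genes Hmgb2, Rrm2 and Pclaf. In B220+ and B220- cells Vim was at -1.88 and -0.30 log2 within IgM cells and -1.75 and -1.85 within IgG cells. Within IgA cells Vim was at -3.39 and -4.38, so its ratio in B220- cells depended on the isotype. Lists that were independent of each other would share 0.29 genes higher and 1.90 lower. A further 25 genes passed the rule in opposite directions, against 0.93 and 0.59 if independent, and 7 of these were left without the genes of the library split. Across the 3519 genes tested in both comparisons, which are not independent replicates, the log2 ratios had Pearson's r = -0.007 and Spearman's rho = 0.249, and r = 0.219 without the split genes. Scaled to all UMIs, 0 genes were higher and 10 lower in both. Among IgM cells 3 of the 6 genes higher in both kept 2-fold, and each kept 1.5-fold. The count of genes higher in both also fell without the cycling clusters. Slpi in B220+ cells was at 0.87 log2 without the cycling clusters and 0.48 when scaled to all UMIs.

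**Figure D2:**
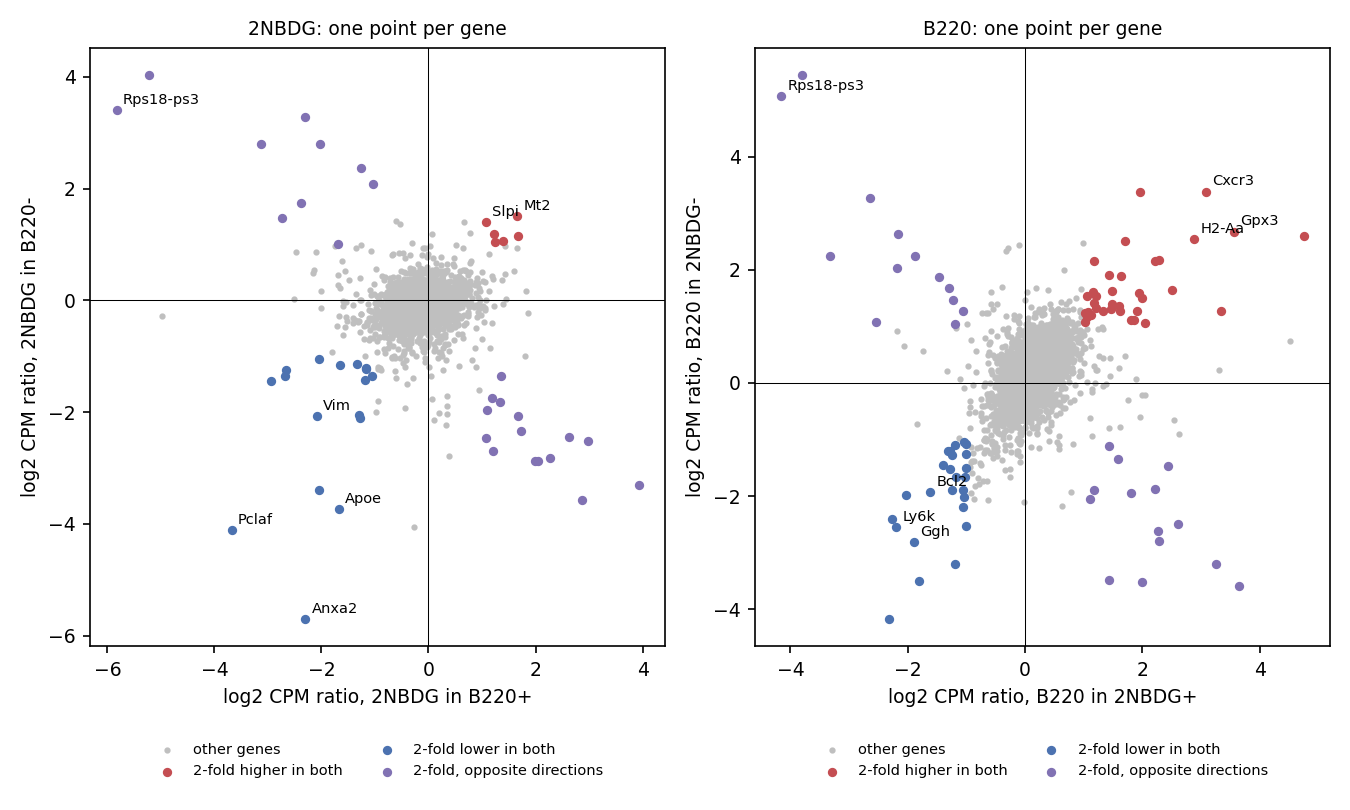
Log2 CPM ratio of each gene tested in both comparisons of a pair, for 2NBDG (in B220+ against in B220- cells) and for B220 (in 2NBDG+ against in 2NBDG- cells), with genes past the 2-fold rule in both marked by direction. The rule was passed the same way by 23 genes for 2NBDG and 60 for B220, and in opposite directions by 25 and 27.

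Class II genes and the chemokine receptor gene Cxcr3 stood out in the B220 comparisons. Among 2NBDG+ splenic cells, B220+ cells had 11.8-fold more Gpx3, an extracellular glutathione peroxidase (8.33 to 17.2), 10.1-fold more Apoe (8.05 to 12.7), 9.90-fold more of the signalling receptor Slamf6 (6.05 to 17.3) and 8.51-fold more Cxcr3, a receptor for inflammatory chemokines (6.33 to 11.7). The class II gene H2-Aa was 7.35-fold higher (6.5 to 8.35). Lower in B220+ cells were the transporter gene Spns3 (4.97-fold, 3.57 to 7.05), Mt2 (4.83-fold, 4.14 to 5.65), the cysteine protease gene Ctsw (4.79-fold, 3.35 to 6.99), Ly6k (4.58-fold, 4.09 to 5.14) and Tnfrsf17, which encodes the survival receptor BCMA (1.58-fold, 1.46 to 1.71). Ptprc, the gene of the sorted protein, was 1.26-fold higher (1.05 to 1.51). A 3' count does not separate the B220 form from other forms of CD45.

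In this comparison 92 genes were higher and 57 lower of 3714 tested, 10 and 8 of them genes of the library split. The MHC class II list had a median of 2.04, with 6 of 7 members 2-fold higher, and the unfolded protein response (0.45, 22 of 26 above 0) and translocation lists (0.40, 23 of 25 above 0) were also higher. Mzb1, an endoplasmic reticulum chaperone of antibody chains, was at 0.81, Hsp90b1 at 0.93 and Lman1 at 0.73 log2. The immediate early (0.34), homing (0.30) and cell cycle lists (0.74) were higher, the last of them not without the cycling clusters or among IgM cells alone, the homing list not when scaled to all UMIs or without clusters with few genes per cell, and the immediate early list not among IgM cells. Lower were the inhibitory receptor list (-0.33), mitochondrially encoded genes (-0.17), plasma cell identity (-0.14) and integrated stress response (-0.13), of which the last pair did not stand apart among IgM cells. The split was 32 higher and 50 lower when scaled to all UMIs and 82 higher and 95 lower without Jchain.

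Among 2NBDG- splenic cells, the B220+ library was set apart by dividing cells. Plk1, a mitotic kinase, was 31-fold higher (14 to 85.3; 242 against 6 UMIs), Cdk1, which drives entry into mitosis, 25-fold (16.0 to 41.2) and Mki67 5.59-fold (4.31 to 7.34). Pbk had 210 against 3 UMIs, a ratio of 53.8 (18.2 to 263). Cxcr3 was 10.5-fold higher (7.97 to 14), Gpx3 6.41-fold (4.92 to 8.48), H2-Aa 5.83-fold (5.39 to 6.31) and Hk2 3.81-fold (2.37 to 6.41; 104 against 21 UMIs). Lower were Spns3 (18.1-fold, 11.2 to 31), the peptidase gene Cpq (11.3-fold, 7.45 to 17.8), the folate enzyme gene Ggh (7.01-fold, 6.15 to 8.03), Jchain (2.30-fold, 2.29 to 2.31), Slc3a2 (2.13-fold, 2.07 to 2.20) and Tnfrsf17 (2.00-fold, 1.87 to 2.14).

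Of 4023 genes tested 238 were higher and 128 lower, 8 and 10 of them genes of the library split. Of 31 cell cycle genes 29 were 2-fold higher (median 3.11), and 7 of 8 class II genes (median 1.72). The translocation (0.62), tricarboxylic acid cycle (0.59), unfolded protein response (0.52), glycolysis (0.62), lipid synthesis (0.55) and nuclear oxidative phosphorylation (0.43) lists were higher than matched lists. The glycolysis and oxidative phosphorylation lists did not stand apart without the cycling clusters, nor glycolysis with the mean over cells, oxidative phosphorylation when scaled to all UMIs, or lipid synthesis with TMM factors, with the mean over cells, without Jchain or among IgM cells alone. Plasma cell identity (-0.37), integrated stress response (-0.33), inhibitory receptors (-0.25), B cell identity (-0.23), mitochondrially encoded genes (-0.11), survival (-0.07) and immediate early genes (-0.04) were lower than matched lists, and their medians turned positive when scaled to all UMIs. Of these, inhibitory receptors, B cell identity and mitochondrially encoded genes did not stand apart without the cycling clusters or with the mean over cells, the first pair also not among IgM cells alone, and inhibitory receptors also not when scaled to all UMIs. The split was 812 higher and 24 lower when scaled to all UMIs and 173 higher and 219 lower without Jchain. Without the cycling clusters 115 genes were higher.

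In both B220 comparisons 35 genes were higher and 25 lower, where independent lists would share 3.31 and 1.39. Cxcr3 (ENSMUSG00000050232; chromosome X, 101731535 to 101734269), Gpx3, H2-Aa (ENSMUSG00000036594; chromosome 17, 34282744 to 34287823), H2-Ab1, H2-Eb1, the adhesion gene Cd2 and Scimp, an adaptor that binds class II signalling complexes, were higher in both. H2-Ab1 was 4.84-fold (4.61 to 5.08) and 4.52-fold (4.35 to 4.70) higher, H2-Eb1 4.63-fold and 4.46-fold, Cd2 5.64-fold and 3.12-fold and Scimp 3.12-fold and 3.74-fold in 2NBDG+ and 2NBDG- cells. Lower in both were Spns3, Ly6k (5.83-fold in 2NBDG- cells, 5.21 to 6.55), Mt2, Ggh, Cpq, Wnt10a, Ly6d (2.65-fold, 2.55 to 2.76, and 2.74-fold, 2.65 to 2.84) and the survival gene Bcl2 (ENSMUSG00000057329; chromosome 1, 106538178 to 106714274), at 3.07-fold (2.60 to 3.63) and 3.82-fold (3.30 to 4.44). The B220+ libraries held more IgG cells, and the shares of IgG move with these genes. A further 27 genes went in opposite directions, against 2.54 and 1.81 if independent, and 9 of them were left without the genes of the library split. Across 3587 genes Pearson's r was 0.273 and Spearman's rho 0.448, and r was 0.473 without the split genes. The counts in both were 15 higher and 7 lower when scaled to all UMIs.

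**Figure D3:**
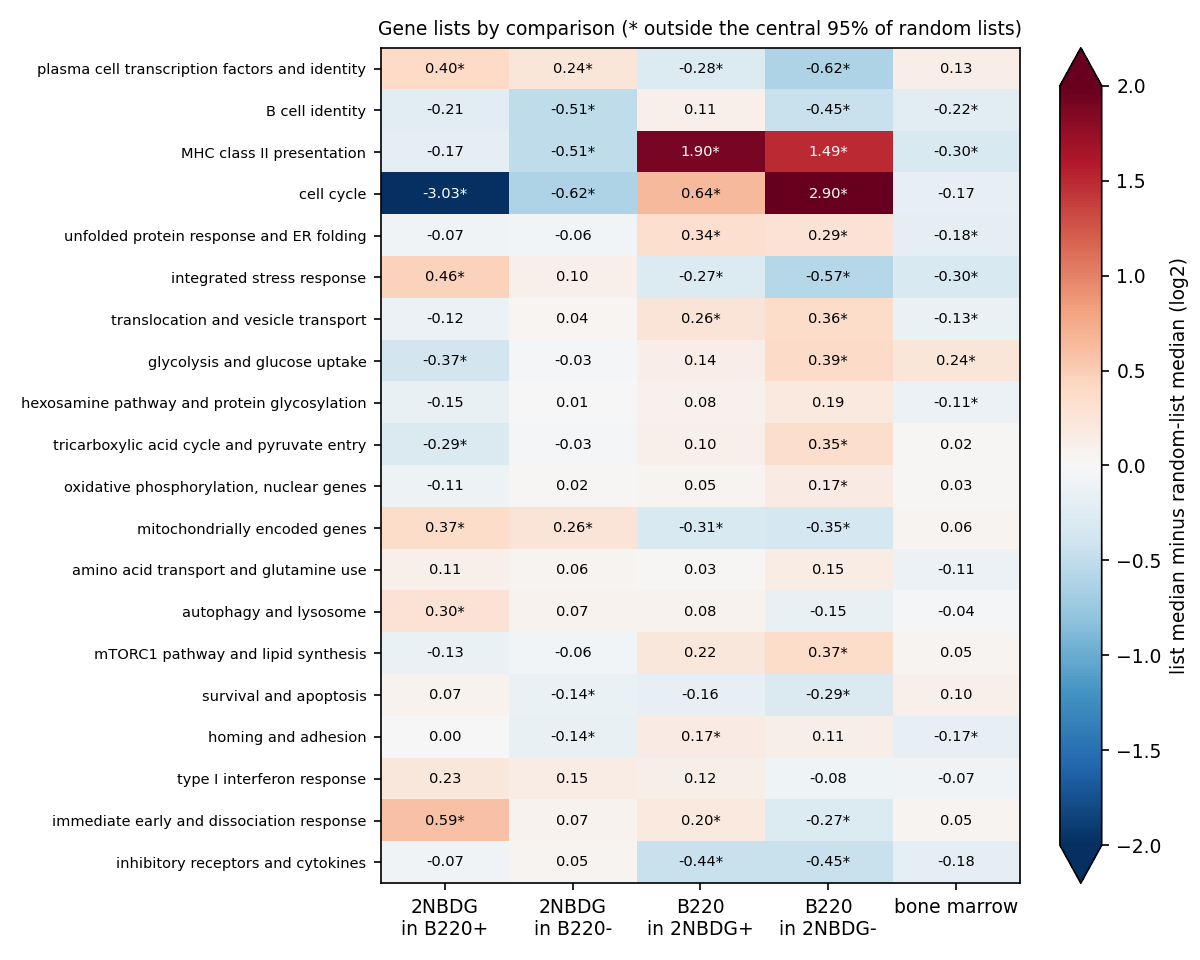
Median log2 CPM ratio of each of the 20 gene lists (vertical axis) minus the median of its matched random lists, in the 5 comparisons (horizontal axis). Lists apart from 10000 matched random lists are marked. MHC class II genes were higher in B220+ cells in both comparisons (1.90 and 1.49 above random lists). Cell cycle genes were lowest for 2NBDG in B220+ cells (-3.03).

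Bone marrow plasma cells differed from splenic cells of the same gate in metallothioneins. Mt1 (ENSMUSG00000031765; chromosome 8, 94179082 to 94180327) was 4.14-fold higher in bone marrow (3.92 to 4.37; 1624 against 392 CPM) and Mt2 2.92-fold (2.70 to 3.17). Ccr9 and Ccr10, receptors for chemokines of the gut and of mucosal epithelia, were 2.54-fold (1.89 to 3.44) and 2.32-fold (2.07 to 2.62) higher. Within IgA cells, however, Ccr10 was at 0.11 log2 and Ccr9 at 0.46, while Mt1 was at 1.68 to 3.11 log2 within each isotype. Within IgG cells the Ccr9 counts lay at or near the floor (-0.68 log2), so its direction there could not be told. Ggh was 3.37-fold higher (3.10 to 3.66). The kinase gene Matk had 182 UMIs in bone marrow and 3 in spleen, a ratio of 42.4 (14.3 to 208). Within IgM, IgG and IgA cells Ggh was at 2.64, -0.14 and 1.81 log2 and Matk at 6.14, 0.74 and 0.23. Matk had no more than 3 splenic UMIs within any isotype, so its ratios rest on the floor. Lower in bone marrow were Serpina3f (4.19-fold, 3.29 to 5.4), the IgM receptor gene Fcmr (3.66-fold, 2.61 to 5.23), the selenium carrier gene Selenop (3.33-fold, 2.98 to 3.73), Spon1 (3.33-fold, 2.63 to 4.23), Plac8 (3.01-fold, 2.49 to 3.66) and H2-Aa (2.20-fold, 1.82 to 2.68). Sdc1 (1.12-fold, 1.06 to 1.19) and Tnfrsf17 (1.26-fold, 1.18 to 1.34) were slightly higher. The share of IgA cells was also higher in bone marrow, 59.0% against 23.9%.

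Of 3490 genes tested 41 were higher and 49 lower, 10 and 8 of them genes of the library split, and with TMM factors 53 were higher and 33 lower. The splenic B220-2NBDG- library lies on the same side of the split as bone marrow, and 14 genes were 2-fold higher and 22 lower in bone marrow than in both B220- splenic libraries, a count added after the data were seen. These included Mt1, Mt2, Matk, Ccr9, Ccr10, Ggh, Hmox1, Fosb and Phlda1 on the higher side and Lag3, Cd9, Pou2f2, Pfkp, H2-Aa, H2-Q7, Fcmr and Plac8 on the lower. Of those named as higher, Mt1, Mt2 and Hmox1 kept 2-fold against both libraries within each isotype. Matk, Phlda1, Ccr9, Ccr10 and Ggh did so only within IgM cells. Within IgG cells Phlda1 and Ccr9 both stood at -0.92 log2 against B220-2NBDG- cells, the ratio that the floor alone gives. They could not be judged there, and Matk had 0.76 and 1.17 CPM in the splenic B220-2NBDG+ and B220-2NBDG- libraries. Both counts were smaller when scaled to all UMIs, and fewer genes were lower with TMM factors. The unfolded protein response list was lower than matched lists (-0.27, 25 of 26 members below 0), as were translocation (-0.25, 24 of 25 below 0), integrated stress response (-0.45), MHC class II (-0.43), B cell identity (-0.35), homing (-0.32) and hexosamine and glycosylation genes (-0.25). The glycolysis list had a median of 0.07 (percentile 99.8), and -0.04 when scaled to all UMIs. Among IgM cells alone the MHC class II, B cell identity, translocation, glycolysis and homing lists did not stand apart, nor did the hexosamine list when scaled to all UMIs, with TMM factors, without Jchain or without clusters with few genes per cell, the homing list when scaled to all UMIs or with the mean over cells, or MHC class II with the mean over cells.

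Cells with cell cycle transcripts were concentrated in 1 library. After each cell was thinned to 1000 non-immunoglobulin UMIs, 15.4% of B220+2NBDG- cells (13.4 to 17.6; 186 of 1208) held at least 3 cell cycle UMIs. The share was 1.71% (1.03 to 2.66) in B220+2NBDG+ cells, 1.48% (0.895 to 2.31) in B220-2NBDG- cells, 0.224% (0.027 to 0.808) in splenic B220-2NBDG+ cells and 0.107% (0.003 to 0.594) in bone marrow. Thinning left out 2 to 13 shallower cells per library, and the unthinned shares were 34.4%, 15%, 9.65%, 7.72% and 9.81% in the same order. Within B220+2NBDG- cells the share was 13.4% (10.9 to 16.1) among IgM, 18.9% (15.3 to 23.0) among IgG and 12.0% (5.64 to 21.6) among IgA cells, and these intervals overlap.

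**Figure D4:**
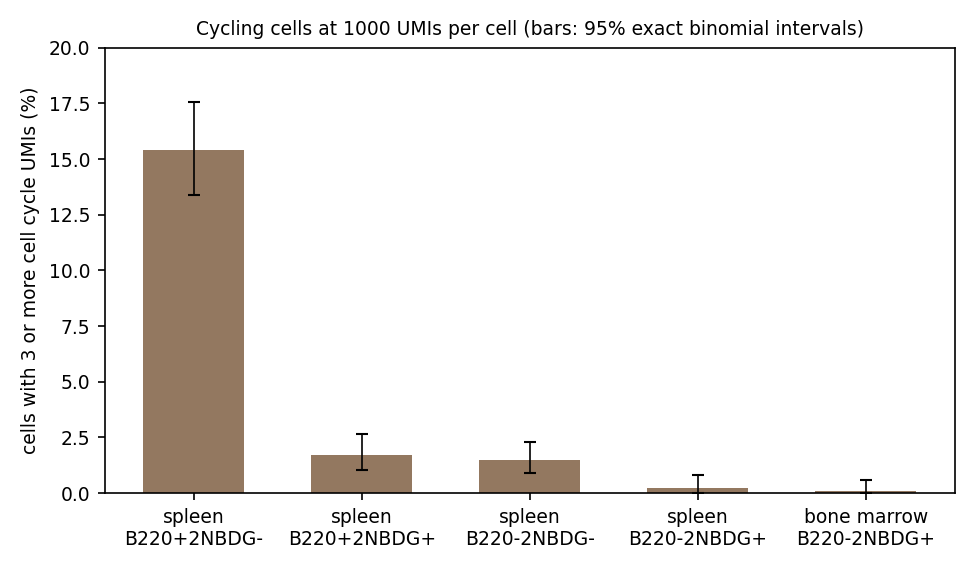
Share of cells, in percent, with at least 3 cell cycle UMIs after thinning to 1000 non-immunoglobulin UMIs, per library, with exact 95% binomial intervals that cover counting error only. B220+2NBDG- cells stood at 15.4% and the other 4 libraries at 1.71% or below.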

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

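The search for shared sequence and the removal of doublets were fixed before their results were seen, and all other tests in this part were chosen after the patterns had been noticed.

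In both pairs of splenic comparisons many genes passed the 2-fold rule in opposite directions, 25 for 2NBDG and 27 for B220 (30 genes in all), and this difference between the paired comparisons was not tested. If gates drove these genes, bone marrow B220-2NBDG+ cells would lie nearer to the splenic library of their own gate, but they did so for 1 of the 30 genes (3.33%). Thinning all libraries to 3950427 UMIs left 104% of the 2NBDG count, which argues against depth. Of the 29 genes with a sequence, 69.0% shared at least 50% of the 31-base words of their last 500 bases with another gene, against 4.36% of 4129 other tested genes, a ratio of 15.8, and 6.67% of the 75 genes that went the same way in both comparisons. A candidate explanation is therefore that reads from near-identical copies were assigned differently in the B220+2NBDG- and splenic B220-2NBDG+ libraries, for which the labels name no batch, read length or run, and a biological share of the pattern stays open.

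Cycling cells made up 15.4% of B220+2NBDG- cells after thinning, 8.99 times the highest share of the other libraries, so deeper cells in this library do not account for them. Leaving out predicted doublets kept 98.8% of that share. Only 5 of the library's 1222 barcodes were predicted doublets, too few for their removal to decide whether pairs of cells were read as one. In the cycling cluster of this library the median plasma cell marker stood at 64.6% of its level in the library's other cells, more than dividing cells of another type would bring. A biological candidate is a population of dividing plasmablasts that carries B220 and takes up little 2NBDG, which stays untested because 1 pool of mice gave the library. The gate compared with itself in other mice would test it.

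Isotype shares move with both gates and with tissue, so they may carry part of the gene differences. Among cells called IgM, 90% of the 60 genes that differed the same way in both B220 comparisons (54 genes) and 91.3% of the 23 in both 2NBDG comparisons (21 genes) kept a ratio of at least 1.5 in both, which argues against the isotype mix as the whole cause. A ratio of 2 was kept by 51.7% and 65.2%, so the mix may still account for part of the size. Within IgG cells 5 of the 35 genes higher and 11 of the 25 lower in B220+ cells kept 2-fold, and within IgA cells 8 and 0. A ratio of 1.5 was kept by 18 and 16 of them within IgG cells and by 21 and 1 within IgA cells. The IgG sums of B220+ and splenic B220- cells were unequal, with 2438929 against 314751 UMIs without 2NBDG and 2543075 against 496399 with it. With both counts at the floor of 3 UMIs, this alone gives a lower ratio, as for Spns3 (-2.95 log2 in 2NBDG- cells). The IgG counts of higher and lower genes therefore cannot be set against each other. Of the 25 lower genes 12 kept their direction within IgA cells. No minimum count was set within isotypes, so some of the others were not measured there. Cpq and Clec2i each stood at 1.08 and 0.52 log2 within IgA cells, the ratios that the floor alone gives for these sums. The IgA counts therefore do not show how many of these differences were absent. For bone marrow 72.2% of 36 genes kept 1.5-fold and 52.8% kept 2-fold among IgM cells, which lies between the share set for a cause in the isotype mix (at most 50% keeping 2-fold) and the share set against it (at least 80% keeping 1.5-fold), so isotype and tissue cannot be told apart for these genes as a set. Single genes differ in this: Mt1 was higher in bone marrow within IgM (2.07 and 3.49 log2), IgG (1.68 and 2.93) and IgA cells (3.11 and 3.76), while Ccr10 was at 0.11 and -0.32 within IgA cells.

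Immediate early genes were higher than matched lists in B220+ cells among 2NBDG+ cells (median 0.34) and lower among 2NBDG- cells (median -0.04), and this difference was not tested. Igkv UMIs, which the comparisons of genes do not use, numbered 1.66 per 100 Igkc UMIs in B220+2NBDG- cells, 17.6 in B220-2NBDG-, 9.56 in B220+2NBDG+, 3.36 in splenic B220-2NBDG+ and 8.57 in bone marrow cells, and the lowest 2 values are those of the libraries that stand apart in the gene split. Their differences were not tested.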

How the results depend on the processing

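Alternatives added after the data were seen were leaving out Jchain, the library-split genes or clusters with few genes per cell, cells called IgM alone, another partner for bone marrow, and all settings of the isotype test and of the count against both B220- splenic libraries; the others were planned. No paired test between groups was made, since each group had 1 library, and the ratios between groups come from no test. For 106 ratios of named genes, 970 of 1056 values under the alternatives stayed on the same side of the 2-fold rule. Of the rest, 74 were no longer past it in the same direction, 12 were newly past it and 0 changed direction. Many of these genes were named for their high or low ratios, so staying past the rule is partly built in. The alternatives with no cell filter and with T cell-like cells kept used the same cells, since all barcodes passed the filter. The CPM minimum moved most counts further than the other alternatives, the total used for scaling also moved them, since immunoglobulin and Jchain shares differ between libraries, and low-count genes such as Slc2a1 and Hk2 (21 to 104 UMIs in the spleen) are limited by depth. For all changes given below the cause was not tested, except that a lower threshold or minimum admits more genes. Leaving out cells or genes leaves fewer to call, but some counts rose. Leaving out Jchain also moved the total used for scaling.

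Scaled to all UMIs, 2NBDG in B220+ cells gave 8 higher and 708 lower genes, 2NBDG in B220- cells 31 lower, B220 in 2NBDG+ cells 32 higher, B220 in 2NBDG- cells 812 higher and 24 lower, and bone marrow 21 higher; 0 higher and 10 lower in both 2NBDG comparisons, 15 and 7 in both B220 comparisons, and 4 and 8 in bone marrow against both B220- libraries. The mean over cells gave 110 lower for 2NBDG in B220+ cells. A threshold of 1.5 gave 144 higher and 576 lower, 73 and 191, 336 and 139, 847 and 262, and 78 and 218 in the 5 comparisons (2NBDG in B220+, 2NBDG in B220-, B220 in 2NBDG+, B220 in 2NBDG-, bone marrow), 14, 55 and 44 (higher, lower, opposite) in both 2NBDG and 158, 66 and 48 in both B220 comparisons, and 33 and 113 for bone marrow against both. Without the CPM minimum these were 440 and 750, 252 and 615, 628 and 391, 887 and 764, 390 and 381, then 53, 139 and 130, 197, 142 and 118, and 131 and 179. Without cycling clusters 2NBDG in B220+ cells gave 63 lower, B220 in 2NBDG- cells 115 higher, and 3 genes were higher in both 2NBDG comparisons.

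Without Jchain there were 88 higher for 2NBDG in B220+ cells, 50 higher for 2NBDG in B220- cells, 95 lower for B220 in 2NBDG+ cells, 219 lower for B220 in 2NBDG- cells and 45 lower in both B220 comparisons. Among IgM cells alone bone marrow gave 75 higher and, against both libraries, 34 higher; 3 genes were higher in both 2NBDG comparisons, 23 higher and 16 lower in both B220 comparisons, and 4 and 5 lists stood apart for 2NBDG in B220- cells and for bone marrow. Without the library-split genes 7 and 9 genes stayed in opposite directions for 2NBDG and B220. With TMM factors 10 genes were lower in bone marrow than in both B220- libraries, and with B220-2NBDG- cells as partner 97 were lower in bone marrow.

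With 90% dominance, IgM shares were 31.1% in B220+2NBDG+ cells and 26.0% in bone marrow, IgG shares 19.1% and 4.69%, against 32.6% in B220+2NBDG- cells, and the IgA share 4.02% in B220+2NBDG+ cells. Cycling shares, in the order B220+2NBDG-, B220-2NBDG-, B220+2NBDG+, splenic B220-2NBDG+ and bone marrow, were 11.3%, 0.695%, 0.893%, 0.0% and 0.0% thinned to 500 UMIs, 34.4%, 9.65%, 15%, 7.72% and 9.81% not thinned, and 19.5%, 4.21%, 4.78%, 2.35% and 0.963% with at least 2 UMIs. With at least 5 UMIs they were 13.0% in B220+2NBDG-, 0.811% in B220+2NBDG+ and 0.0% in bone marrow cells. Among IgM cells they were 13.4% in B220+2NBDG-, 0.920% in B220+2NBDG+ and 0.0% in splenic B220-2NBDG+ and bone marrow cells. At Leiden resolution 2 no cluster was named T cell-like, so the share was 0.0% in B220+2NBDG-, B220-2NBDG- and B220+2NBDG+ cells. This value comes from the naming of clusters. Ms4a4b, Trbc2 and Cd3g were among the leading genes of a cluster of 191 cells, 157 of them B220+2NBDG-, which may hold the T cell-like cells.

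In the isotype test, no library block gave 148 higher and 171 lower genes in IgA and 13 and 40 in IgG cells. IgA cells had 713 lower without a filter and 616 lower without TMM factors, and DESeq2 gave 184 higher and 209 lower in IgG cells. Without the cluster led by Anxa2, an alternative added last, 257 were higher and 367 lower in IgA cells and 318 and 417 in IgG cells. Leaving out each library in turn gave 254 to 319 higher and 300 to 349 lower in IgA cells, and 159 to 352 higher and 232 to 421 lower in IgG cells; the lowest IgG counts, 159 and 232, came without B220+2NBDG+ cells, which hold the most IgG cells.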

Other observations

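The comparison of isotypes within libraries, its gene lists and its splits were all chosen after the data had been seen. It used edgeR's quasi-likelihood test on sums of cells, paired within the 5 libraries (n = 5 per isotype), with Benjamini-Hochberg adjustment.

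IgA and IgM plasma cells of the same libraries differed in homing genes. In IgA cells the chemokine receptor gene Ccr10 rose by 4.27 log2 (SE 0.26, adjusted p = 2.6e-07), the membrane binding protein gene Anxa2 by 5.71 (SE 0.29, adjusted p = 6.5e-08), the gut-homing integrin gene Itgb7 by 3.59 (SE 0.33, adjusted p = 7.2e-06), Ccr9 by 3.51 (SE 0.34, adjusted p = 1.2e-05) and the transcription factor gene Klf2 by 3.08 (SE 0.35, adjusted p = 4.5e-05), each in 5 of 5 libraries by edgeR. A cluster led by Anxa2, Klf2 and Itgb7 held 71.4% and 70.4% of the IgA cells of B220+2NBDG- and B220-2NBDG- spleen, 13.8% and 0.935% of those of B220+2NBDG+ and B220-2NBDG+ spleen and 0.0% of those of bone marrow. Without it Anxa2 was at 3.76 log2 (SE 0.39, adjusted p = 9.9e-07, 4 of 5 libraries), Klf2 at 1.85 (SE 0.19, adjusted p = 1.1e-06, 5 of 5) and Itgb7 at 2.69 (SE 0.20, adjusted p = 2.1e-08, 5 of 5) by edgeR, so part of their folds came from this cluster, while Ccr10 stayed at 4.04 (SE 0.25, adjusted p = 1.6e-09, 5 of 5). Lower in IgA cells were the peptidase Cpq (log2 fold -3.99, SE 0.26, adjusted p = 2.6e-07), the IgM receptor Fcmr (-3.57, SE 0.27, adjusted p = 1.4e-06), the inhibitory receptor Lag3 (-2.97, SE 0.24, adjusted p = 2.5e-06) and the selenium carrier Selenop (-2.76, SE 0.18, adjusted p = 2.6e-07), each in 5 of 5 libraries by edgeR. Of 21 homing genes 10 rose and 5 fell, the same numbers when adjusted over the list alone. Of 14 integrated stress response genes 4 fell, and 6 adjusted over the list alone. In all, 361 genes rose and 400 fell of 7603 tested, 249 and 376 of them in 5 of 5 libraries.

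IgG and IgM cells differed in genes of class II presentation and of the integrated stress response. Slpi rose in IgG cells by 2.86 log2 (SE 0.13, adjusted p = 3.4e-14, 5 of 5 libraries) and Cxcr3 by 1.85 (SE 0.24, adjusted p = 4.3e-06, 5 of 5 libraries) by edgeR. Lower in IgG cells were the inhibitory receptor Btla (log2 fold -3.55, SE 0.30, adjusted p = 4.3e-09), the phosphatase Ptpn6 (-2.22, SE 0.12, adjusted p = 4.3e-13), Bcl2 (-1.98, SE 0.18, adjusted p = 1.8e-08), Tnfrsf17 (-1.76, SE 0.15, adjusted p = 4.1e-09) and Slc3a2 (-1.41, SE 0.11, adjusted p = 1e-09), each in 5 of 5 libraries by edgeR. Cxcr3 and Bcl2 thus differ with both B220 and isotype. The B220 ratios of Slpi fell to 0.42 and 0.42 log2 within IgM cells and 0.09 and -0.06 within IgG cells. Of 8 class II genes 6 rose (6 adjusted over the list alone), of 20 cell cycle genes 11 (14), of 26 unfolded protein response genes 8 rose and 1 fell (12 and 1), of 25 translocation genes 5 rose (12), and of 12 integrated stress response genes 9 fell (10). In all 316 genes rose and 410 fell of 7893 tested, 245 and 350 of them in 5 of 5 libraries; without B220+2NBDG+ cells the counts were 159 and 232, and with DESeq2 184 and 209.

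Chance was weighed by regrouping the 10 sums of each test into 5 and 5, with 100 of the splits drawn per test. For IgA against IgM 1 of 100 splits, the real one, gave as many as 761 genes, and the highest of the others gave 122. For IgG against IgM it was likewise 1 of 100, with 726 genes and a highest other of 180. Most of these splits do not keep the pairing of sums by library. Only 16 splits put 1 sum of each library on either side, as the real split does, which is too few for a share under 0.05; in these the highest other count was 0 for IgA and 1 for IgG.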
